A study of Homo sapiens with 10 samples.

How the data were processed

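Total RNA from 786-O cells, a human clear-cell renal carcinoma line, was hybridised to Affymetrix arrays after infection with lentivirus and selection with puromycin at 2 ug/ml, per the labels' protocols. RNA was extracted with a Qiagen kit and labelled by the standard Affymetrix procedure, per the labels' protocols. The design has 5 groups of 2 arrays, which are the scrambled control, ZHX2 hairpin 44 and ZHX2 hairpin 45 in one deposited table of 6 arrays, and control shRNA and p65 shRNA in another deposited table of 4 arrays. Groups and replicate numbers were taken from the sample titles. The labels do not say how the control shRNA of the p65 table relates to the scrambled control of the ZHX2 table, so the 2 tables were never fitted together. Per the submitters' processing notes the deposited values are RMA signals, that is, background-corrected, normalized and summarised per probe set, and they lie on the log2 scale. The software behind RMA, its version, the probe annotation and the genome build are not given in the sources used here.

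Each deposited table holds log2 signals for 53617 probe sets with identical identifiers. Array medians lay between 6.15 and 6.22 in the ZHX2 table and between 1.87 and 1.89 in the p65 table, where 13 to 20 probe sets per array were below 0. The tables are recorded under different array platforms and their medians differ. They were therefore taken as normalized separately, and no level was compared between them. Within the ZHX2 table the interquartile range ran from 2.80 to 2.94, so the arrays did not share identical distributions, and a further quantile normalization was among the alternatives. No background or detection measure was used here, so no probe set was called absent. The number of arrays limits the precision.

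Probe sets were named by joining the platform annotations of both tables, which give a single gene for 16098 and 23862 probe sets. Of 14704 with a single gene in both, 14595 had the same gene (99.3%). Symbols were updated through the RefSeq gene table of the human assembly GRCh38.p14, which was used for names only, and an annotated symbol was updated for 608 probe sets. This named 24461 probe sets with 1 gene, and left 27196 with no gene in either annotation, 1851 with several and 109 with different genes unnamed. For the 1080 of 22443 genes with over 1 probe set, the one with the highest mean signal over the arrays of the table was used. No probe set was removed for low signal in the main comparisons.

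Comparisons were made in R 4.3.3 with limma 3.58.1 by linear models of group means and empirical Bayes moderation without an intensity trend or robust fitting. All 6 ZHX2 arrays entered one fit with 3 residual degrees of freedom, with contrasts of each hairpin and of the mean of both hairpins against scrambled, and of hairpin 45 against hairpin 44. The 4 p65 arrays entered a separate fit with 2 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p of a gene is from limma. Standard errors are the moderated ones of limma, and group errors are SD over 2 arrays. A set of 28 gene lists, written from general knowledge before the data were examined, was tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, with adjustment over the lists of a comparison, and again with the correlation estimated from the arrays and with fry. With the correlation estimated, camera has only the fit's residual degrees of freedom, 3 or 2, and so little power. At the preset value it treats genes as nearly independent, so its p can be very small. Counts of list members adjusted over the list alone stand beside those adjusted over all genes.

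Named genes followed a fixed rule. ZHX2 and RELA were always given, with the 8 largest rises and 8 largest falls among called genes whose arrays did not overlap between sides, for the mean of both ZHX2 hairpins and for p65, leaving out microRNA, small nucleolar RNA, pseudogene and uncharacterised genes. The rule also took the 2 list members with the smallest p for each list, the 5 shared calls per direction with the largest smaller change for ZHX2 and p65, and the 5 largest differences per direction between the hairpins. As the p65 comparison made 0 calls, its genes and the shared genes were taken by the same rule from the planned intensity-trend alternative.

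Overlap with shared controls was set against 100 simulations of unchanged groups, and overlap between ZHX2 and p65 calls was tested with one-sided Fisher's exact tests adjusted over 4 directions. Alternatives were an intensity trend, robust moderation, median centring, quantile normalization, a filter keeping probe sets at or above the 40th percentile of the table's mean signal, the mean of a gene's probe sets, every probe set, the replicate number as a block, array weights, a 1.5-fold minimum, fits of only the 2 groups compared, and each array left out. The fit was tested on simulated data with the real means, 22443 genes and 100 changed genes per size. With variances falling with signal as in the real arrays, the test of the mean of both hairpins called 82% of genes changed by 1 and 99% of those changed by 2 on the log2 scale. The p65 test called 0% and 43%, and with an intensity trend 22% and 75%, and no call had the wrong sign. Unchanged genes called for p65 were 0 without the trend and 6 with it. With variances the same at every signal, the p65 test called 0% and 59% with and without the trend. These shares hold for the number of changed genes simulated and may differ where more genes change.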

Results

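Genome-wide expression was measured on 10 arrays of 786-O cells, an established line of human clear-cell renal carcinoma that lacks functional VHL. The cells carried lentiviral short hairpin RNAs against ZHX2, a zinc-finger and homeobox transcription factor, or against p65, the NF-kB subunit encoded by RELA. The arrays fell into 5 groups of 2. The ZHX2 table held a scrambled control, ZHX2 hairpin 44 and ZHX2 hairpin 45 on 6 arrays, and the p65 table held its own control shRNA and p65 shRNA on 4 arrays. Each array gave 53617 log2 signals, of which 24461 could be assigned to a single gene, for 22443 genes. The median signal lay between 6.15 and 6.22 on the ZHX2 arrays and between 1.87 and 1.89 on the p65 arrays. Since the tables are recorded under different platforms and were taken as normalized separately, no level was compared between them. Across genes, the 2 arrays of a group correlated with r of 0.993 for scrambled, 0.995 for hairpin 44 and 0.995 for hairpin 45, and with r of 0.985 for the p65 control and 0.987 for the p65 hairpin. The SD of the difference between the 2 arrays was 0.239, 0.202 and 0.197 in the ZHX2 groups, and 0.427 and 0.40 in the p65 groups. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical, and the number of arrays limits the precision.

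ZHX2 was measured first, as the targeted gene, by the probe set 17072295. Its signal was 10.58 and 10.43 on the scrambled arrays, 9.35 and 9.38 with hairpin 44, and 8.93 and 9.03 with hairpin 45. The mean was 10.51 ± 0.103 (SD, n = 2) in scrambled cells, 9.37 ± 0.0243 with hairpin 44 and 8.98 ± 0.0671 with hairpin 45. The log2 change was -1.14 with hairpin 44 (SE 0.0862, limma adjusted p = 0.00528) and -1.53 with hairpin 45 (SE 0.0862, limma adjusted p = 0.000927), on 2 arrays against 2. The difference of -0.39 between the hairpins did not pass the test (limma adjusted p = 0.152). RELA, by the probe set 16740495, was higher on the ZHX2 knockdown arrays, at 9.64 and 9.68 with hairpin 44 and 9.82 and 9.75 with hairpin 45, against 9.34 and 9.23 in scrambled cells. Its mean change over both hairpins was 0.44 (SE 0.0689, limma adjusted p = 0.0112), and this call was lost without scrambled replicate 2 (adjusted p = 0.0554). In the p65 table RELA stood at 7.64 and 7.67 on the control arrays and at 5.04 and 5.28 on the p65 hairpin arrays, a log2 difference of -2.50 (SE 0.178, limma adjusted p = 0.073). That difference passed the test when limma's moderation followed the intensity trend (adjusted p = 0.00131). ZHX2 was 7.75 and 7.82 on the control arrays and 7.60 and 7.79 on the p65 hairpin arrays, a difference of -0.09 (SE 0.175, limma adjusted p = 0.861).

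**Figure D1:**
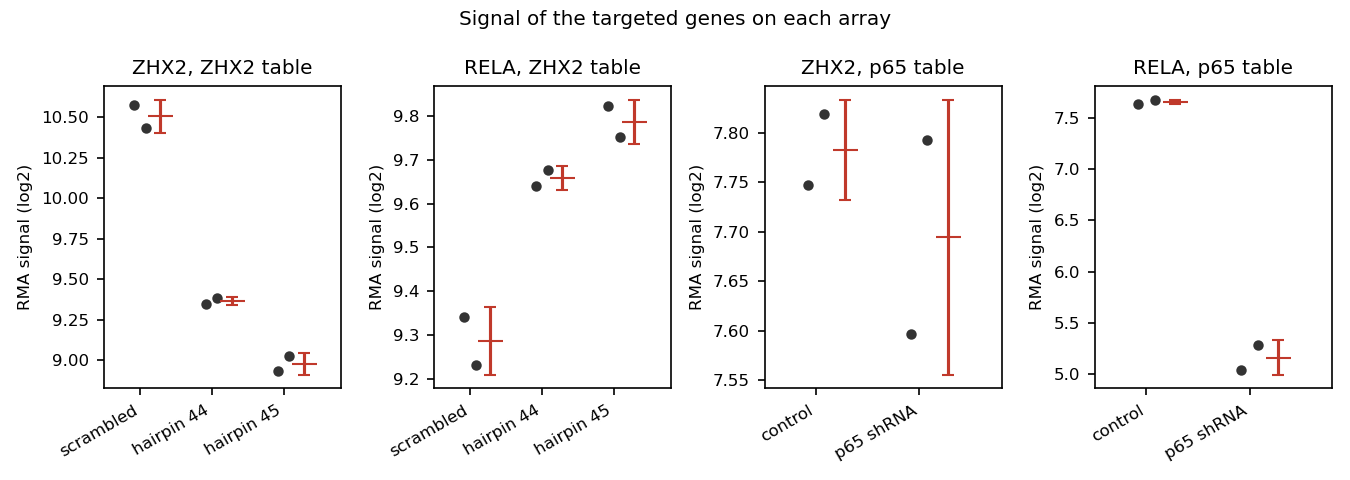
Log2 RMA signal of ZHX2 and RELA on each array (black points) with the group mean and SD of 2 arrays (red), in the ZHX2 table (left pair of panels) and the p65 table (right pair), each panel on its own axis that does not start at 0. ZHX2 averaged 10.51 in scrambled cells against 9.37 and 8.98 with the ZHX2 hairpins, and RELA averaged 7.66 in control cells against 5.16 with the p65 hairpin.

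The comparison of the mean of both ZHX2 hairpins (4 arrays) with scrambled cells (2 arrays) asked which genes depend on ZHX2 in these cells. The largest rise was in TMEM158, a membrane protein induced by RAS signalling, by 2.63 on the log2 scale (SE 0.0644, limma adjusted p = 0.000381), to signals of 10.13 and 10.24 with the hairpins from 7.55. It was followed by FLG, which encodes filaggrin, at 1.86, the YAP target ANKRD1 at 1.81, the secreted glycoprotein STC2 at 1.67, the organic anion transporter SLCO4A1 at 1.67, the long noncoding RNA MANCR at 1.46, ZNF175 at 1.32 and the nucleolar protein LYAR at 1.31. The largest falls were in the matrix metalloproteinases MMP7 at -3.04 (SE 0.144, limma adjusted p = 0.000856) and MMP13 at -3.02 (SE 0.103), the potassium channel KCNJ16 at -2.79, PLXDC2 at -2.66 and the ectonucleotidase ENPP3 at -2.58. The chemokines CXCL8 and CXCL10 fell by 2.44 and 2.43 and the interferon-induced IFI44L fell by 2.43, with standard errors of 0.111, 0.180 and 0.0994.

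With both hairpins averaged, 4103 of 22443 genes passed the limma threshold of adjusted p under 0.05, 2664 higher and 1439 lower. Of these, 1038 changed at least 1.5-fold (599 higher, 439 lower) and 183 at least 2-fold (62 higher, 121 lower). At an unadjusted p under 0.05 there were 7222 genes, against 1122 from chance alone. The higher share of the calls was 64.9%, 53.2% after a further quantile normalization of the deposited values and 73.0% after median centring. With 1 array left out the count fell to 1789 without scrambled replicate 2, to 2259 and 2146 without hairpin 44 replicates 1 and 2, and to 2175 and 2075 without hairpin 45 replicates 1 and 2.

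Most interferon-stimulated genes fell after ZHX2 knockdown, while the NF-kB and antigen presentation lists between them held genes that fell, genes that rose and genes that were not called. Of the 27 measured interferon-stimulated genes, 16 fell and 0 rose (21 and 0 adjusted over the list alone), with a median log2 change of -0.60 (limma camera adjusted p = 3.93e-12; adjusted p = 0.114 with an estimated correlation). OAS1, a sensor of double-stranded RNA, fell by 1.31 (SE 0.0795). Of 23 NF-kB-induced cytokines, chemokines and adhesion molecules, 7 fell and 0 rose (9 and 0 adjusted over the list alone), among them CXCL8 and the monocyte chemoattractant CCL2 at -2.26 (SE 0.115). That list's median was -0.20 (camera adjusted p = 0.00108; adjusted p = 0.114 with an estimated correlation). Among 16 NF-kB subunits and feedback regulators, 6 fell and 1 rose, over all genes and adjusted over the list alone, with the inhibitor-like NFKBIZ at -1.34 and the deubiquitinase TNFAIP3 at -0.98. Their median was -0.08 (camera adjusted p = 0.0187; adjusted p = 0.322 with an estimated correlation). Without scrambled replicate 1 this list was no longer past the threshold (adjusted p = 0.126) and its median was 0.00556. In the antigen presentation list 3 of 13 genes fell and 1 rose (9 and 1 adjusted over the list alone), with a median of -0.22 (camera adjusted p = 0.00108; adjusted p = 0.114 with an estimated correlation). B2M fell by 0.36 and the peptide transporter subunit TAP2 rose by 0.32, but B2M lost its call when any array except scrambled replicate 1 was left out (adjusted p from 0.0516 to 0.0875, log2 change from -0.40 to -0.32 over all omissions), and TAP2 when any array was left out (adjusted p from 0.0596 to 0.105, log2 change from 0.29 to 0.34) or after quantile normalization (0.0673). The remaining TNF and NF-kB response genes went both ways, with 5 of 22 higher and 7 lower (7 and 7 adjusted over the list alone), the complement component C3 at -1.86 and the adhesion receptor CD44 at 0.84, and the list as a whole did not pass (camera adjusted p = 0.29). The upstream NF-kB kinases and adaptors also split, with 3 of 19 higher and 3 lower by either adjustment, the receptor IL1R1 at -1.22 and the kinase CHUK at 0.78 (camera adjusted p = 0.99).

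Lists of proliferation, protein synthesis, stress response and energy metabolism passed the camera test toward higher values. All 25 G1/S and DNA replication genes rose, over all genes and adjusted over the list alone, by a median of 0.62. The replication initiation factor MCM10 stood at 0.94 (SE 0.0712) and the transcription factor E2F1 at 0.75 (SE 0.0606), and the camera adjusted p was 4.7e-16, and adjusted p = 0.176 with an estimated correlation. Of 26 G2/M and mitosis genes 19 rose and 0 fell (21 and 0 adjusted over the list alone), among them CDC20 at 0.54 and the mitotic kinase PLK1 at 0.48. Their median was 0.35 (camera adjusted p = 1.75e-10; adjusted p = 0.281 with an estimated correlation). Cytosolic ribosomal protein genes rose in 10 of 15 cases with 0 falls (14 and 0 adjusted over the list alone), among them RPS16 at 0.58 and RPS23 at 0.39. Their median was 0.32 (camera adjusted p = 2.53e-06; adjusted p = 0.114 with an estimated correlation). Oxidative phosphorylation had 7 of 18 genes higher and 0 lower (11 and 0 adjusted over the list alone), among them the complex I subunits NDUFB3 at 0.53 and NDUFS3 at 0.56. Their median was 0.24 (camera adjusted p = 9.09e-06; adjusted p = 0.265 with an estimated correlation). NDUFB3 lost its call without scrambled replicate 2 (adjusted p = 0.0596), while its change stayed between 0.49 and 0.58 with any 1 array left out. Amino acid and integrated stress response genes, targets of ATF4, rose in 12 of 21 cases and fell in 2 (12 and 3 adjusted over the list alone), among them STC2 and the cystine transporter SLC7A11 at 1.17. Their median was 0.43 (camera adjusted p = 0.000371; adjusted p = 0.114 with an estimated correlation). The endoplasmic reticulum chaperone list had 6 of 16 genes higher by either adjustment, among them SDF2L1 at 0.52 and XBP1 at 0.51, a transcription factor of the unfolded protein response and not a chaperone. Their median was 0.18 (camera adjusted p = 0.000233; adjusted p = 0.114 with an estimated correlation). NRF2 antioxidant genes rose in 8 of 17 cases with 0 falls (9 and 2 adjusted over the list alone), SLC7A11 and the glutathione synthesis gene GCLM at 0.69 among them. Their median was 0.20 (camera adjusted p = 0.00237; adjusted p = 0.287 with an estimated correlation). Glycolysis genes rose in 6 of 18 cases with 0 falls (7 and 1 adjusted over the list alone), with HK2 at 0.53 and PGK1 at 0.47. Their median was 0.19 (camera adjusted p = 0.0101; adjusted p = 0.403 with an estimated correlation), a call that ended after quantile normalization (adjusted p = 0.138).

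The cholesterol, p53 target and proximal tubule lists passed the camera test toward lower values, with most p53 targets and tubule markers not called. Cholesterol biosynthesis and uptake genes fell in 10 of 18 cases with 0 rises (12 and 0 adjusted over the list alone), with HMGCS1 at -0.73 and the sterol feedback regulator INSIG1 at -0.69. Their median was -0.32 (camera adjusted p = 4.44e-06; adjusted p = 0.114 with an estimated correlation). p53 target genes fell in 6 of 19 cases and rose in 1 (8 and 3 adjusted over the list alone), with TP53INP1 at -1.23 and PHLDA3 at -0.57. Their median was -0.11 (camera adjusted p = 0.0187; adjusted p = 0.287 with an estimated correlation), a call lost without scrambled replicate 1 (adjusted p = 0.0939). In the proximal tubule list 5 of 17 genes fell and 0 rose (5 and 1 adjusted over the list alone). Its members with the smallest p were the cadherins CDH6 at -1.92 and CDH16 at -1.11. How specific each member is to the proximal tubule was not tested. The list median was -0.15 (camera adjusted p = 0.00108, and adjusted p = 0.114 with an estimated correlation). With a correlation estimated from the arrays, none of the 15 lists past the camera threshold kept its call. That test has only 3 residual degrees of freedom, so these losses cannot tell a weak list from low power. The other lists did not pass camera, though some of them passed fry, as given below. HIF-responsive genes split, with 5 of 24 higher and 4 lower (5 and 6 adjusted over the list alone), ENPP3 and IGFBP3 at -0.87 (camera adjusted p = 0.423). Extracellular matrix and mesenchymal genes had 4 of 26 higher and 8 lower (4 and 10 adjusted over the list alone), with the YAP-regulated CCN2 at 1.14 and CCN1 at 1.04 against a list median of -0.13 (camera adjusted p = 0.0565). A second, dimmer CCN2 probe set changed by 0.13. The matrix list was past the camera threshold with an intensity trend (adjusted p = 0.025), median centring (0.0473), quantile normalization (0.0118) and without dim probes (0.0352). It also passed fry (adjusted p = 0.0161). Immediate early genes had 9 of 21 higher and 3 lower by either adjustment, with FOSL1 at 1.06 and EGR1 at -1.29 (camera adjusted p = 0.0592). A second, dimmer EGR1 probe set changed by -0.23. Apoptosis regulators had 4 of 18 higher and 5 lower (4 and 6 adjusted over the list alone), with PMAIP1 at 1.08 and BCL2L11 at -0.95 (camera adjusted p = 0.548).

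Among fatty acid synthesis genes 2 of 11 rose and 1 fell (2 and 2 adjusted over the list alone), with ELOVL5 at 0.43 and SCD at -0.42 (camera adjusted p = 0.99). Replication-dependent histones rose in 2 of 7 cases (3 adjusted over the list alone), H1-5 at 0.61 and H2BC14 at 0.37 (camera adjusted p = 0.0826, past the threshold with an intensity trend at 0.0443 and without scrambled replicate 1 at 0.0148). The H1-5 call ended without either scrambled array, either hairpin 44 array or hairpin 45 replicate 1 (adjusted p from 0.0526 to 0.177) and after quantile normalization (0.0521), and the H2BC14 call without scrambled replicate 2, either hairpin 44 array or either hairpin 45 array (adjusted p from 0.0812 to 0.179) and after quantile normalization (0.139). With 1 array left out H1-5 ran from 0.46 to 0.77 and H2BC14 from 0.24 to 0.50. In the zinc-finger homeobox and VHL pathway list 2 of 12 rose and 1 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.548). CUL2 and ZHX3, both at 0.31, lost their calls when any single array was left out (adjusted p from 0.061 to 0.0759 and from 0.0734 to 0.114, at changes from 0.30 to 0.33 and from 0.26 to 0.36), and after quantile normalization (0.0811 and 0.1). A second, dimmer ZHX3 probe set changed by 0.09, and with the mean of its probe sets ZHX3 changed by 0.20 and lost its call (limma adjusted p = 0.107). Among markers of other cell types few passed. Of 19 leukocyte markers 1 fell, CD68 at -0.46 (camera adjusted p = 0.275), of 10 fibroblast markers 1 fell, LUM at -0.95 (0.0742, and 0.0451 without dim probes), and of 10 neuronal and embryonic kidney markers 1 fell, NEFL at -1.16 (0.171), with the same counts adjusted over the list alone. With an intensity trend 2 fibroblast markers fell. With hairpin 45 alone 2 leukocyte and 2 fibroblast markers fell (1 and 2 adjusted over the list alone). Of 12 endothelial markers 0 passed limma (0 adjusted over the list alone, 0 with an intensity trend, camera adjusted p = 0.218). List median, mean and camera direction differed in sign for fatty acid synthesis, apoptosis regulators and NF-kB kinases, none of which passed.

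**Figure D2:**
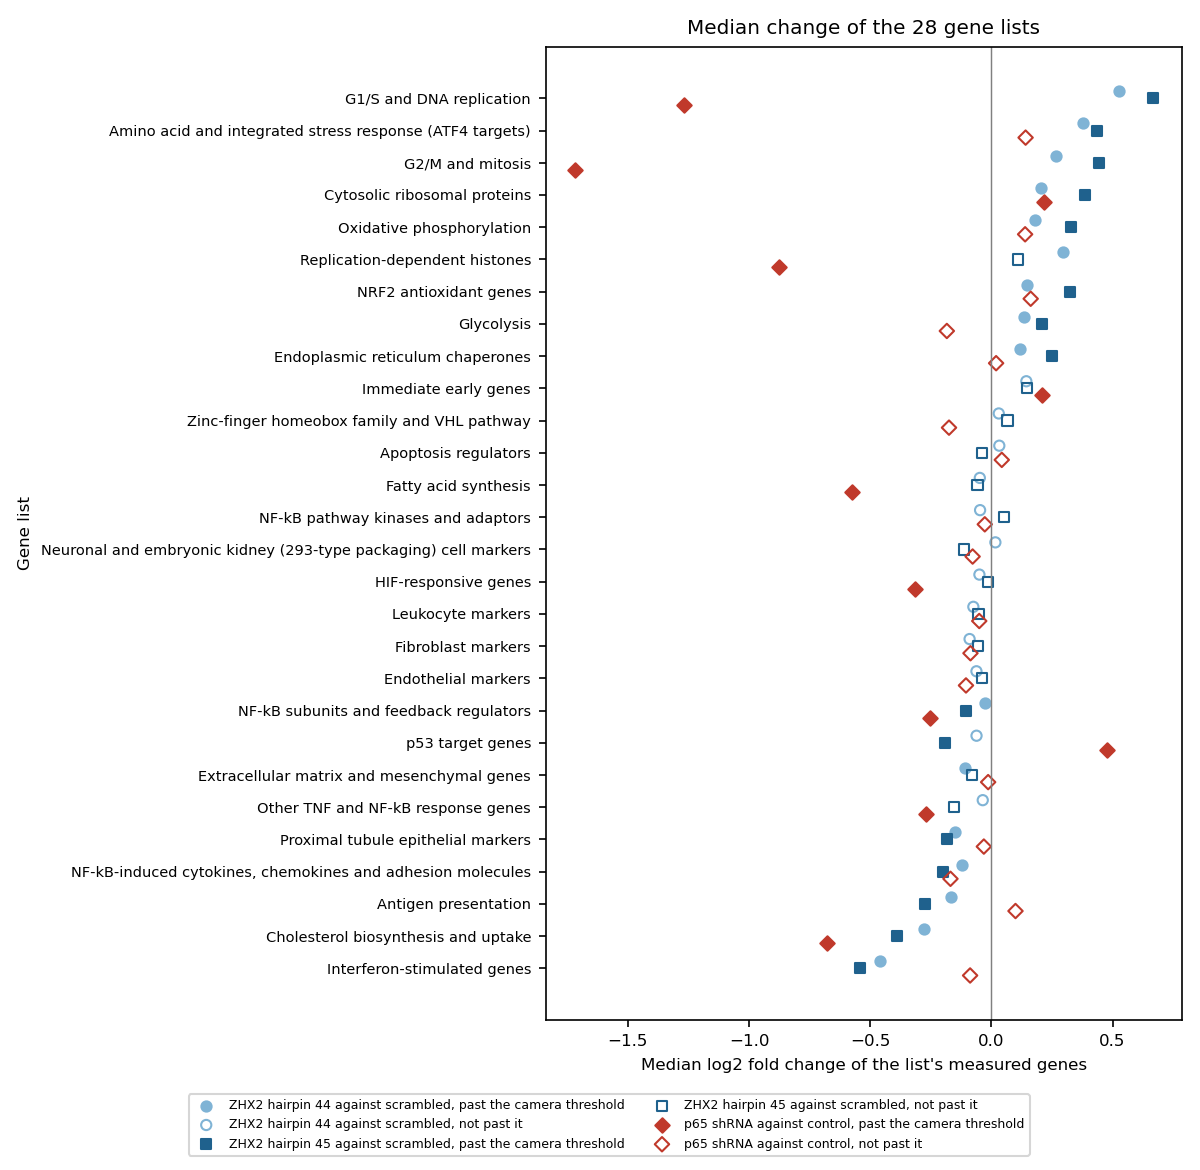
Median log2 fold change over the measured genes of each of the 28 gene lists, for ZHX2 hairpin 44 (light circles) and hairpin 45 (dark squares) against scrambled and for the p65 hairpin (red diamonds) against its control, with filled symbols where the list passed the camera threshold at the preset correlation. The G1/S list lies at 0.53 and 0.67 with the ZHX2 hairpins and at -1.27 with the p65 hairpin.

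Taken one by one against the same scrambled arrays, most genes called with hairpin 44 were also called with hairpin 45, but most hairpin 45 calls were not called with hairpin 44. Hairpin 45, which left less ZHX2 signal, changed 4515 genes by limma (2919 higher, 1596 lower), and hairpin 44 changed 1717 (1078 higher, 639 lower). Both hairpins called 1562 genes in the same direction, 1004 higher (93.1% of the hairpin 44 calls) and 558 lower (87.3%), against 140.2 and 45.4 for independent lists, and 3 genes in opposite directions. These 1562 stand among 4515 hairpin 45 calls. Log2 changes correlated with r = 0.812 and rho = 0.753 across genes, which are not independent replicates, with a covariance of 0.0743. In 100 simulations of unchanged groups against shared controls, with noise independent between genes, r averaged 0.501 (highest 0.526), rho 0.456 and the covariance 0.0114. There limma called 0 shared genes, which was nearly fixed in advance because no simulated gene changed. The simulations held no shift of the scrambled arrays common to many genes, so they cannot show how many of the 1562 calls come from such a shift. At an unadjusted p under 0.05, 4308 genes were shared with the same sign, against 365.6 in the simulations. With 1 scrambled array for each hairpin, a split chosen after the data were seen, r was 0.556 or 0.579, rho 0.45 or 0.488 and the covariance 0.0587 or 0.0615. Calls were not counted under that split, and part of their excess may come from the shared controls. Counts fell with single arrays left out. Without scrambled replicates 1 and 2, hairpin 44 called 603 and 96 genes, without its own replicates 3 and 4, and without either hairpin 45 array 578. Without scrambled replicate 2 most of these calls were lower, at 32 higher and 64 lower for hairpin 44 and 29 higher and 63 lower for the shared calls. Shared calls were 579 and 92 without scrambled replicates 1 and 2, 3 and 4 without the hairpin 44 replicates, and 484 and 477 without the hairpin 45 replicates. Hairpin 45 called 2640 genes without scrambled replicate 2, and 1247 and 1132 without its own replicates 1 and 2. After quantile normalization 51.2% of hairpin 44 calls and 53.1% of hairpin 45 calls were higher, and after median centring 69.7% and 73.6%, against 62.8% and 64.7%.

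The hairpins also differed from each other. By limma, 89 genes differed between hairpin 45 and hairpin 44 (2 arrays each), 29 higher and 60 lower with hairpin 45. The balance turned with the intensity trend, where 1468 genes differed, 921 higher and 547 lower. It was near even without dim probes, at 198 higher and 206 lower. The extracellular matrix protein TNC was 1.43 higher with hairpin 45 (SE 0.0751, limma adjusted p = 0.00687), having fallen by 1.02 with hairpin 44 against scrambled and risen by 0.41 with hairpin 45. The proximal tubule transporter SLC17A3, TINAG and the kynurenine pathway enzyme KMO were lower with hairpin 45 by -1.91, -1.90 and -1.89 (SE 0.0730, 0.0742 and 0.0726, limma adjusted p = 0.00204 for each). This count was 3 without scrambled replicate 1 or replicate 2, 4 without hairpin 45 replicate 1, and 0 by limma without either hairpin 44 array or hairpin 45 replicate 2, where the full set of arrays gave 3386 genes at an unadjusted p under 0.05. TNC lost its call whichever array was left out (adjusted p from 0.0529 to 0.139), and SLC17A3, TINAG and KMO without either hairpin 44 array or hairpin 45 replicate 2 (adjusted p from 0.0574 to 0.0594). The differences themselves moved little, from 1.39 to 1.47 for TNC, -1.94 to -1.88 for SLC17A3, -1.90 to -1.89 for TINAG and -1.93 to -1.86 for KMO. Scrambled arrays do not enter this contrast. Leaving out either of them therefore kept each difference as it was and altered only the estimate of spread and its degrees of freedom.

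The comparison of the p65 hairpin with its control, 2 arrays against 2, asked which genes depend on p65. The planned limma test called 0 of 22443 genes, with a smallest adjusted p of 0.073. At an unadjusted p under 0.05 there were 3218 genes (1435 higher, 1783 lower), against 1122 from chance, and 199 genes (46 higher, 153 lower) had a limma adjusted p under 0.1. Moderation with an intensity trend, chosen beforehand as another setting, called 868 genes (308 higher, 560 lower). Among alternatives chosen after the data were seen, 109 genes (18 higher, 91 lower) passed when protein-coding genes alone were tested, and 1048 with the trend and a filter on dim probes together. The count was 0 with robust moderation, median centring, quantile normalization, the dim filter alone, the mean of a gene's probes, every probe, the replicate block, array weights, the platform's own names, a 1.5-fold minimum, and any 1 array left out. The genes named for this comparison were chosen from the intensity-trend calls after their values were seen. Lower genes included the monocyte chemoattractant CCL2 at -4.50 (SE 0.498, adjusted p = 0.073, and 0.00299 with the trend), the copper carrier CP at -3.11, the adhesion molecule VCAM1 at -2.91 (SE 0.168, adjusted p = 0.073, and 0.0006 with the trend), ZNF724 at -2.80, the mitotic protein HMMR at -2.57, BTN3A3 at -2.52, RELA, and ALOX5AP, which serves leukotriene synthesis, at -2.40. Higher genes included UGT2A3 at 3.52 (SE 0.515, adjusted p = 0.0946, and 0.0079 with the trend), whose control arrays lay at 2.83 and 1.25. Others were the stress cytokine GDF15 at 2.91 (SE 0.286), SYT11 at 2.67, NRCAM at 2.61, MMP13 at 2.55, CPA4 at 2.46, PCDHB13 at 2.32 and RAB39B at 2.28. With 1 array left out CCL2 ran from -5.19 to -3.82 and CP from -3.76 to -2.45. The hairpin means of CCL2, CP, ZNF724 and BTN3A3 were 3.51, 3.37, 2.91 and 1.12. The control means of UGT2A3, NRCAM, PCDHB13 and RAB39B were 2.04, 2.73, 2.38 and 1.69. Array medians were 1.87 to 1.89 over all probe sets and 2.83 to 2.89 over named genes. With no background measure, the sizes of such differences and their order are not established.

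In the p65 comparison the cell-cycle, cholesterol, fatty acid, histone and HIF lists, the NF-kB regulators and the other TNF and NF-kB genes passed the camera test toward lower values, but not the NF-kB-induced cytokines or the NF-kB kinases. The fry test, which does not compare a list with other genes, gave another picture. There the NF-kB-induced cytokines passed, and the NF-kB regulators and other TNF and NF-kB genes kept their calls. The G1/S (fry adjusted p = 0.0852), G2/M (0.0709), cholesterol, fatty acid, histone and HIF lists did not pass fry (0.0666 to 0.212). No list member passed limma over all genes, so list counts are given adjusted over the list alone and, in brackets, with the intensity trend over all genes. All 26 G2/M and mitosis genes were lower by the first count [23], with HMMR and the kinesin KIF23 at -1.82 (SE 0.171) as examples. Their median was -1.72, with a camera adjusted p of 1.3e-30 (adjusted p = 0.515 with an estimated correlation). Of 25 G1/S and DNA replication genes 22 were lower [21], with CLSPN at -1.88 and CDC45 at -1.77. Their median was -1.27 (camera adjusted p = 3.84e-20; adjusted p = 0.515 with an estimated correlation). A second, dim CLSPN probe set differed by -0.03. Cholesterol genes were lower in 11 of 18 cases [9], with LSS at -1.71 and FDPS at -1.29. The median was -0.68 (camera adjusted p = 1.86e-08; adjusted p = 0.515 with an estimated correlation). Fatty acid synthesis genes were lower in 6 of 11 cases and higher in 1 [4 and 0], with SCD at -1.11 and ELOVL5 at -0.82. The median was -0.57 (camera adjusted p = 0.00296; adjusted p = 0.515 with an estimated correlation). Histone genes were lower in 4 of 7 cases [4], with H2BC14 at -2.06 and H1-5 at -1.87 (median -0.88, camera adjusted p = 0.00348; adjusted p = 0.582 with an estimated correlation). NF-kB subunits and feedback regulators were lower in 6 of 16 cases [3], with TNFAIP3 at -1.51 and the inhibitor NFKBIA at -0.97 (median -0.25, camera adjusted p = 0.00851; adjusted p = 0.515 with an estimated correlation). Other TNF and NF-kB response genes were lower in 5 of 22 cases and higher in 2 [3 and 1], with PTX3 at -1.82 and CD44 at -1.14. The median was -0.27 (camera adjusted p = 0.0325; adjusted p = 0.515 with an estimated correlation). HIF-responsive genes were lower in 1 of 24 cases [1], the angiogenic factor VEGFA at -1.06, while EGLN3 at -0.87 did not pass. The median was -0.32 (camera adjusted p = 0.00851; adjusted p = 0.569 with an estimated correlation).

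The p53 target, immediate early and ribosomal protein lists passed camera toward higher values after p65 knockdown, but not fry (fry adjusted p = 0.0852, 0.22 and 0.212). Of 19 p53 targets 7 were higher adjusted over the list alone [5], with GDF15 and TP53INP1 at 1.08 (median 0.48, camera adjusted p = 0.00168; adjusted p = 0.515 with an estimated correlation). Immediate early genes were higher in 4 of 21 cases [2], with MYC at 1.07 and DUSP6 at 0.81 (median 0.21, camera adjusted p = 0.0233; adjusted p = 0.582 with an estimated correlation). Of 15 ribosomal protein genes 0 passed limma adjusted over the list alone [0], RPS23 standing at 0.66 and RPL19 at 0.39 (median 0.22, camera adjusted p = 0.0237; adjusted p = 0.582 with an estimated correlation). Several of the 11 list calls were lost with 1 array left out. Without control replicate 1 the ribosomal (median 0.0966, adjusted p = 0.193) and immediate early (0.161, adjusted p = 0.145) lists were lost. Without control replicate 2 the histone (-0.681, adjusted p = 0.0549), HIF (-0.173, adjusted p = 0.0981) and other TNF and NF-kB (-0.137, adjusted p = 0.0606) lists were lost. Without p65 replicate 1 the immediate early list was lost (0.272, adjusted p = 0.0763). Without p65 replicate 2 the immediate early (0.228, adjusted p = 0.114), ribosomal (0.235, adjusted p = 0.14), HIF (-0.281, adjusted p = 0.0653) and other TNF and NF-kB (-0.257, adjusted p = 0.0813) lists were lost, while the ATF4 list passed (0.182, adjusted p = 0.033). The other TNF and NF-kB list was also lost with the intensity trend (0.055) and without dim probes (0.0577).

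NF-kB-induced cytokines did not pass as a list at -0.17 (camera adjusted p = 0.0852, 5 of 23 lower and 1 higher adjusted over the list alone, 5 lower with the trend), but did with the trend (0.0433) and without dim probes (0.0379). The list also passed fry (adjusted p = 0.0191). VCAM1 and CCL2 were among its members. Interferon-stimulated genes stood at a median of -0.09 (camera adjusted p = 0.619, 1 of 27 lower adjusted over the list alone), with OAS3 at -1.70 and ISG15 at 0.50. Antigen presentation genes stood at 0.10 (0.36, 0 of 13), ATF4 targets at 0.14 (0.183, 1 of 21 higher), endoplasmic reticulum chaperones at 0.02 (0.604, 1 of 16 higher and 2 lower), NRF2 genes at 0.16 (0.36, 1 of 17 higher and 1 lower), oxidative phosphorylation at 0.14 (0.183, 0 of 18) and glycolysis at -0.18 (0.381, 0 of 18). Matrix and mesenchymal genes stood at -0.01 (0.72, 1 of 26 higher and 1 lower), apoptosis regulators at 0.04 (0.663, 0 of 18), proximal tubule markers at -0.03 (0.604, 0 of 17), the homeobox and VHL list at -0.17 (0.363, 0 of 12) and NF-kB kinases at -0.03 (0.663, 1 of 19 lower). In each bracket the first value is the camera adjusted p and the counts are limma calls adjusted over the list alone. Markers of other cell types gave 0 limma calls adjusted over the list alone and 0 with the trend, with camera adjusted p of 0.663 for 19 leukocyte, 0.663 for 10 fibroblast, 0.36 for 12 endothelial and 0.899 for 10 neuronal and embryonic kidney genes. The median and mean of the apoptosis list differed in sign. The labels do not say whether the p65 arrays shared a hairpin sequence, so no constructs were compared.

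Both knockdowns were then set side by side through calls and fold changes, since they share no array and differ in platform and control. Differences between the knockdowns therefore cannot be told apart from differences of platform or control. The main limma calls shared 0 genes in either direction, because the p65 comparison had none. At an unadjusted p under 0.05 in both, 605 genes moved the same way (317 higher, 288 lower) and 939 the opposite way (639 higher after ZHX2 and lower after p65 knockdown, 300 the reverse). With intensity-trend moderation 71 genes were lower in both, against 49.8 for independent lists (one-sided Fisher's exact test, which treats genes as independent, adjusted p = 0.00148). Among them were CCL2 (-2.26 after ZHX2 and -4.50 after p65 knockdown), VCAM1 (-1.57 and -2.91), LRRC37A3 (-1.75 and -2.20), MAB21L3 (-1.61 and -1.50) and CLEC4E (-1.43 and -2.17). Another 91 were higher in both against 53.3 (adjusted p = 9.12e-08 by the same exact test), among them ANKRD1 (1.81 and 1.62), STC2 (1.67 and 1.45), POLR1F (1.01 and 1.01), MYC (0.86 and 1.07) and UQCRHL (0.83 and 1.09). The opposite directions, counted after the data were seen, were more frequent. With the trend, 329 genes were higher after ZHX2 and lower after p65 knockdown against 96.9 for independent lists (adjusted p = 3.09e-110, exact test), among them the coagulation initiator F3 (1.15 and -1.38), MCM10 (0.94 and -1.75), DDAH1 (0.85 and -0.95), CD44 (0.84 and -1.14) and CLSPN (0.82 and -1.88), while 100 were lower after ZHX2 and higher after p65 knockdown against 27.4 (adjusted p = 1.73e-31, exact test). A second, dimmer CD44 probe set changed by 1.08 after ZHX2 and 0.02 after p65 knockdown. When both fits were repeated with the trend on genes above the dim filter, the calls changed along with the background, and 15308 genes were tested in both. Of these, 128 were higher in both against 101.2 (unadjusted p = 0.00125, exact test) and 95 lower in both against 84.3 (p = 0.114, exact test). Another 380 were higher after ZHX2 and lower after p65 against 170.8 (p = 3.4e-70, exact test), and 117 the reverse against 50.0 (p = 9.56e-20, exact test). Over all 22443 genes the fold changes correlated with r = -0.0654 and rho = -0.0491 across genes, with 48.8% of genes sharing a sign. Without p65 control replicate 1 r was -0.115, and without p65 control replicate 2 it was -0.000756.

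**Figure D3:**
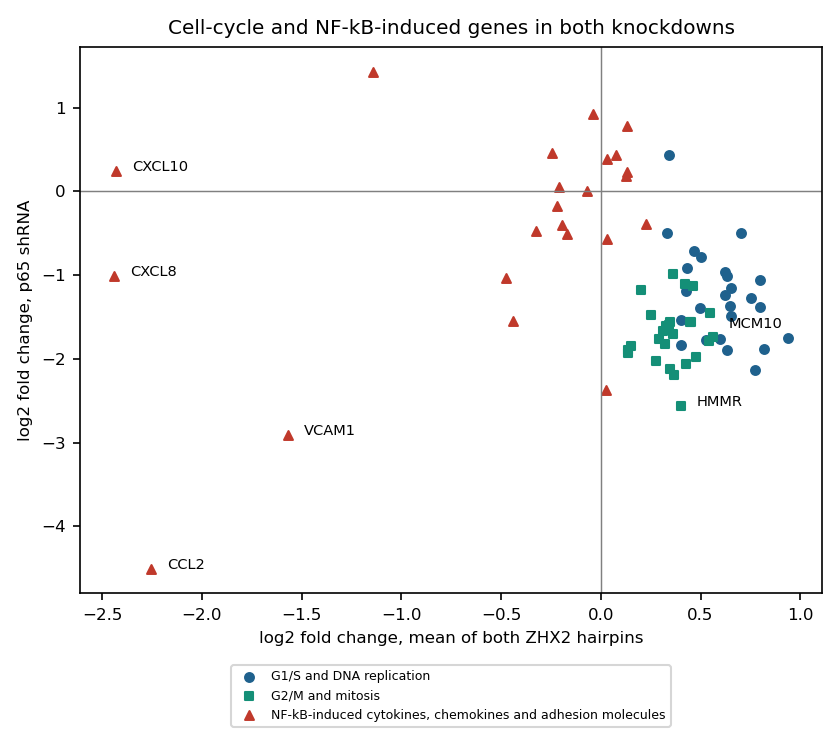
Log2 fold change with the mean of both ZHX2 hairpins (x axis) against log2 fold change with the p65 hairpin (y axis) for genes of the G1/S, G2/M and NF-kB-induced cytokine lists, each point 1 gene. CCL2 and VCAM1 lie low on both axes, at -2.26 and -4.50 and at -1.57 and -2.91, while MCM10 lies at 0.94 and -1.75.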

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

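The tests of the cell-cycle pattern were chosen only after the result was seen, while the test of the difference between the hairpins was planned. Of the tests of that pattern, those of signal and of a single hairpin were first set over both lists jointly and on the deposited values, then split by list, that of signal also by knockdown, and then run after quantile normalization. On the deposited values the G2/M median after ZHX2 knockdown lay 0.108 beyond matched lists, where replicates differed by 0.115.

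Between hairpin 45 and hairpin 44, 89 genes differed by limma. TNC was higher with hairpin 45 by 1.43, NSA2 by 1.02, SERPINB7 by 1.00, GLIPR1 by 0.99 and SCARNA4 by 0.94, with limma adjusted p of 0.00687, 0.0337, 0.0207, 0.0208 and 0.0321. SLC17A3 stood at -1.91, TINAG at -1.90, KMO at -1.89, TNFAIP6 at -1.84 and PDZK1 at -1.64, with limma adjusted p of 0.00204 for the first 3, and 0.00647 and 0.0207. TNC and NSA2 had opposite signs against scrambled, at -1.02 and 0.41 and at -0.71 and 0.31 with hairpins 44 and 45. Leaving out 1 array gave between 0 and 4 such genes. SLC17A3, TINAG and KMO lost their calls without hairpin 44 replicate 1 (adjusted p = 0.0577), hairpin 44 replicate 2 (0.0594) or hairpin 45 replicate 2 (0.0574). TNFAIP6 lost its call without any array but hairpin 45 replicate 1 (0.0562 to 0.117), and the other 6 genes lost theirs whichever array was left out (0.0529 to 0.261). With 1 array left out the differences kept their sign, from 0.88 to 1.16 for NSA2 and from -1.77 to -1.51 for PDZK1, for example.

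Among gene lists, oxidative phosphorylation was higher with hairpin 45 by a median of 0.181 (camera adjusted p = 0.000174; adjusted p = 0.491 with an estimated correlation). Ribosomal proteins were higher by 0.154 (0.000969; adjusted p = 0.39 with an estimated correlation) and endoplasmic reticulum chaperones by 0.146 (0.000635; adjusted p = 0.39 with an estimated correlation). p53 target genes stood at -0.118 (0.000312; adjusted p = 0.4 with an estimated correlation), antigen presentation at -0.105 (0.0144; adjusted p = 0.4 with an estimated correlation) and NF-kB subunits and feedback regulators at -0.0853 (0.00656; adjusted p = 0.491 with an estimated correlation). G2/M genes were higher with hairpin 45 by 0.156 (1.32e-05; adjusted p = 0.491 with an estimated correlation) and G1/S genes by 0.11 (0.0144; adjusted p = 0.58 with an estimated correlation).

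The cell-cycle lists were higher after ZHX2 knockdown, at medians of 0.62 for G1/S and 0.35 for G2/M, and lower after p65 knockdown, at -1.27 and -1.72. Against a normalization difference that depends on signal, after a further quantile normalization the G1/S and G2/M medians lay outside the central range of 1000 lists matched on signal by 0.361 and 0.118 after ZHX2 knockdown and by 1.09 and 1.55 after p65 knockdown, each further than replicate arrays differed (0.0338, 0.0513, 0.372 and 0.334). For G2/M after ZHX2 knockdown the deposited values gave 0.108 against a replicate difference of 0.115. There the outcome depended on the added normalization, which lowered the replicate difference. An effect of 1 ZHX2 hairpin alone is argued against for G1/S, which in the same test lay at least 0.300 above matched lists with each hairpin, with both scrambled arrays and with either, whereas G2/M, with 26 of 26 genes above 0 and medians of 0.266 and 0.443 with hairpins 44 and 45, lay 0.0776 above them with hairpin 44 but 0.0349 without scrambled replicate 2, less than replicates differed, so there the list and such an effect cannot be told apart. A change that grows with ZHX2 depletion stays open, since the difference between the hairpins was 0.11 for G1/S, inside matched lists that reached 0.128, and 0.156 for G2/M, above matched lists that reached 0.125. Scrambled arrays low for these genes would raise both hairpins together and stay open, as do differences in growth or density between cultures, which were not tested.

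Outside the named genes, 1381 of 29156 probe sets without a single gene name changed after ZHX2 knockdown when every probe set was tested, 836 higher and 545 lower.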

How the results depend on the processing

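The platform's own names, protein-coding genes alone, the adjusted p under 0.1, the trend together with the dim filter, the split of the scrambled arrays, and all counts of opposite changes were tests chosen only after the result was seen, and the other settings were planned.

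No list or named gene past the threshold turned its tested direction in the settings run for it, but balances of calls turned. Genes differing between hairpins were 29 higher and 60 lower, against 921 and 547 with the intensity trend and 1150 and 645 with trend and dim filter. Without scrambled replicate 2, hairpin 44 calls went from 1078 higher and 639 lower to 32 and 64, and shared calls from 1004 and 558 to 29 and 63. The median of NF-kB subunits turned from -0.0837 to 0.00556 without scrambled replicate 1, and its call was lost. ZHX2 kept its call in the ZHX2 comparison in each setting run for it (-1.43 to -1.26, limma adjusted p from 4.47e-09 to 0.017). RELA in the p65 comparison ran from -2.62 to -2.38 (adjusted p from 0.000897 to 0.327). It passed with the intensity trend (0.00131), with trend and dim filter (0.000897) and among protein-coding genes (0.0387), and not in the other settings run for it. Robust moderation, median centring, quantile normalization, the mean of a gene's probes and the platform's own names moved no count of calls by over 1.5 times. The trend called 5877 genes for the mean of both hairpins, 3980 of the 4103 main calls among them. Of other values with the trend, 49 named p65 genes gained a call, and with quantile normalization 5 named ZHX2 genes lost theirs. Why the settings moved the counts below was, except for smaller tests or fewer arrays, not looked into, and the cause was not tested. No measure of background was used here, so the sizes of changes of dim probe sets are uncertain in both tables. Replicate differences had an SD of 0.427 and 0.40 in the p65 table.

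With the intensity trend the counts were 3944 for hairpin 44, 1468 between hairpins, 868 for p65, 3493 shared by both hairpins, and 162 the same way and 429 the opposite way for ZHX2 and p65. Removing dim probes gave 3063 for hairpin 44, 404 between hairpins and 2723 shared by both hairpins. Trend and dim filter together gave 4264, 1795, 1048, 3756, 223 and 497 in the order of the trend's counts. Testing every probe gave 521 for hairpin 44, 8 between hairpins and 493 shared by both hairpins. Array weights gave 207 between hairpins. Protein-coding genes alone gave 178 between hairpins, 109 for p65, 12 the same way and 67 the opposite way. A 1.5-fold minimum left 687 for hairpin 44, 1627 for hairpin 45, 1038 for their mean and 585 shared. At an adjusted p under 0.1 p65 gave 199, only the 2 groups compared gave 578 for hairpin 44, and unadjusted p under 0.05 gave 605 the same way and 939 the opposite way. With an estimated correlation camera, left with 3 and 2 residual degrees of freedom and so little power, passed 0 ZHX2 lists and 0 p65 lists, against 15 and 11. The fry test, which does not compare a list with other genes, passed 23 and 3. The 3 for p65 were the NF-kB-induced cytokines, the NF-kB regulators and the other TNF and NF-kB genes. The remaining p65 lists past camera lost their calls with fry (adjusted p from 0.0666 to 0.22). For ZHX2, fry added 8 lists (adjusted p from 0.00484 to 0.0349). These were the other TNF and NF-kB, HIF, matrix, immediate early, leukocyte, fibroblast, neuronal and embryonic kidney, and homeobox and VHL lists.

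Deviations of same-numbered arrays correlated at -0.026, 0.055 and 0.026 in the ZHX2 table and 0.01 in the p65 table, so the numbers were not taken as pairing. With the replicate block the counts were 819 for hairpin 44, 11 between hairpins and 758 shared by both hairpins. The block changed no list call. It ended the calls of 5 genes that differed between hairpins and of ZHX3 (adjusted p = 0.0624).

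With 1 array left out, its lone partner is assumed to vary like the other groups. Such a fit also has fewer residual degrees of freedom, so a call can be lost though the change itself is unmoved. Counts then ran from 3 to 603 for hairpin 44, 1132 to 3973 for hairpin 45, 1789 to 3334 for their mean, 3 to 579 shared by both hairpins and 0 to 4 between hairpins. They stayed at 0 by limma for p65 and for both overlaps, where the full arrays gave 3218 p65 genes at an unadjusted p under 0.05. Lists past the threshold ran from 14 to 16 for ZHX2 and 8 to 10 for p65, and the correlation of fold changes from -0.115 to -0.000756.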

Other observations

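The gene families and the tests of the interferon pattern were chosen only after the result was seen, while the 3 tests of the small nucleolar RNAs were set beforehand. The host-gene test as set also named other host genes, such as DANCR, but was run on the family of genes named SNHG or GAS5.

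Genes that build ribosomes rose with the mean of both ZHX2 hairpins. Of 31 ribosome biogenesis factors 30 rose and 0 fell by limma, with a median of 0.675, NIP7 at 0.99 (SE 0.0616) and the RNA helicase DDX21 at 0.89 (SE 0.0703), and a camera adjusted p of 1.26e-20 (adjusted p = 0.0543 with an estimated correlation). Of 71 mitochondrial ribosomal proteins 39 rose and 0 fell, with a median of 0.324 and MRPL2 at 0.73 (camera adjusted p = 3.7e-18; adjusted p = 0.0543 with an estimated correlation). Cytosolic aminoacyl-tRNA synthetases rose in 11 of 16 cases, with a median of 0.407 and AARS1 at 0.68 (camera adjusted p = 1.09e-08; adjusted p = 0.0734 with an estimated correlation), and proteasome subunits in 18 of 35, with a median of 0.272 and PSMD12 at 0.56 (camera adjusted p = 1.12e-08; adjusted p = 0.124 with an estimated correlation). Host genes of small nucleolar RNAs rose in 12 of 15 cases, with a median of 0.625, SNHG19 at 1.12 and GAS5 at 0.82 (camera adjusted p = 1.36e-08; adjusted p = 0.0543 with an estimated correlation). After p65 knockdown proteasome subunits stood at -0.227 (camera adjusted p = 0.00242; adjusted p = 0.673 with an estimated correlation) and the host genes at 0.241 (camera adjusted p = 0.046; adjusted p = 0.872 with an estimated correlation). Ribosome biogenesis factors at 0.101 (0.729), mitochondrial ribosomal proteins at -0.0164 (0.81) and synthetases at 0.0583 (0.81) did not pass camera there.

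YAP and TEAD target genes rose in 12 of 20 cases and fell in 2 after ZHX2 knockdown, with a median of 0.512, ANKRD1 at 1.81, CCN1 at 1.04 and the ectonucleotidase NT5E at 1.13 (camera adjusted p = 2.24e-05; adjusted p = 0.0543 with an estimated correlation). Complement genes fell in 5 of 11 cases and rose in 2, with C3 at -1.86 and CFI at -2.32 (median -0.255, camera adjusted p = 0.00504; adjusted p = 0.197 with an estimated correlation). Matrix metalloproteinases fell in 4 of 22 cases and rose in 1, with MMP7 at -3.04 and MMP13 at -3.02 (median -0.118, camera adjusted p = 0.000749; adjusted p = 0.0582 with an estimated correlation), while MMP13 stood at 2.55 after p65 knockdown. Of 435 zinc-finger genes named ZNF 52 rose and 13 fell, with a median of 0.0566, and the family did not pass (camera adjusted p = 0.0526). After p65 knockdown none of these 4 families passed camera, at medians of -0.0315, -0.076, 0.012 and 0.0206 with adjusted p of 0.729, 0.729, 0.729 and 0.851. All family medians after ZHX2 knockdown kept their sign under median centring and quantile normalization.

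Interferon-stimulated genes were lower with both ZHX2 hairpins, at medians of -0.461 with hairpin 44 and -0.544 with hairpin 45. With the mean of both hairpins the median was -0.603. A single scrambled array is argued against, since for that mean the median nearest 0 with either scrambled array left out was -0.598. The median over genes of the difference between hairpins was -0.0101, where scaling with the ZHX2 change would give -0.157 and replicate arrays differed by 0.0789. That scaled value takes the measured ZHX2 changes as exact, although the ZHX2 difference between the hairpins did not pass limma. The list medians of -0.461 and -0.544 lie further apart, in the direction of scaling and by slightly more than replicate arrays differed, so these measures disagree. The difference taken gene by gene would be seen if scrambled cells were high for these genes whatever the depletion. A response to ZHX2 loss that is already complete with hairpin 44 would look the same and stays open. Given the list medians, a response that grows with depletion stays open too.

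Small nucleolar RNAs were higher after ZHX2 knockdown, 58 of 215 having risen and 6 fallen, with a median of 0.169 (camera p = 6.38e-06, and p = 0.213 with an estimated correlation). The 773 microRNA and small nuclear RNA genes above a signal floor taken from the small nucleolar RNAs had a median of -0.0293 (30 rose, 42 fell, replicate difference 0.0211). They did not share the rise. They were not otherwise matched on signal, and with no background measure it is not known whether their probe sets measured these RNAs. The same doubt holds for the probe sets of the small nucleolar RNAs. A difference in the recovery of small nucleolar RNAs therefore stays open. The smallest median with 1 array left out was 0.104, where replicate arrays differed by 0.16, so the pattern and 1 deviating array cannot be told apart. Host genes were higher too, at a median of 0.625, as would be seen with higher levels of the transcripts that carry these RNAs. Whether transcription or another step raised them was not tested, so higher transcription stays a hypothesis.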
